A study of Glycine max with 9 samples.

How the data were processed

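RNA of soybean (Glycine max, cultivar Williams 82) was profiled in the unifoliate leaves of 2-week-old seedlings, in 3 libraries each after 0, 1 and 24 h at 4 °C, with at least 6 plants behind each library. The groups and the replicate numbers 1 to 3 were taken from the sample titles, and all 9 libraries were used. Total RNA was made into libraries with a TruSeq RNA kit, per the labels' protocols.

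The deposited table holds 1 score per gene and library, a normalized read count that the authors rounded to whole numbers. Its name says that the counts were normalized. The submitters' processing notes name cutadapt 1.2.1 and DESeq 1.12, with no role or order. The aligner, the read counter, the genome build and the annotation were not given in the sources used here, nor was it stated whether reads shared by near-identical genes were counted. Median-of-ratios factors computed again from the values lay between 1.0057 and 1.0074 in the 9 libraries, so the scores were already on a common scale by that measure.

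The low scores of each library fell on evenly spaced steps, and the spacing gave the worth of 1 read. It was 2.52, 4.15 and 1.55 in replicates 1, 2 and 3 at 0 h, 2.72, 2.69 and 1.34 at 1 h, and 1.57, 1.17 and 1.65 at 24 h. Between 81.3% and 95.9% of the scores from 1 to 40 fell on a whole number of reads, with the rounding of each step as the tolerance, and a minority fell midway between steps. A smaller step covers more of the whole numbers from 1 to 40 by construction. These shares therefore cannot be compared between libraries. Whole reads were therefore not recovered, and no count test was used. Dividing each total by the worth of 1 read gave an estimated depth, and the estimate erred by at most 0.167% in 6 simulated libraries. Those libraries had few scores midway between steps, and the step of 1.17 in replicate 2 at 24 h lay below the steps simulated. The error in the real libraries may therefore be larger. Over the 36 pairs of libraries the lowest difference was 2.8 times counting noise, so no library was treated as a copy of another.

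Scores were analysed as log2(score + 1), so the fold change of a low gene is understated. Genes with a mean of at least 10 over the 9 libraries were kept, which left 38985 of 49777 genes, while 10792 fell below that minimum. Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with trend and robust moderation), two-sided, in 1 fit of all 9 libraries so that the groups shared an estimate of the spread. P values were adjusted by the Benjamini-Hochberg method over all genes kept, with a threshold of 0.05. Every adjusted p-value given is from limma unless another test is named. The SE of a log2 change is limma's moderated one, except where counting alone is named. It draws on all 9 libraries and on the spread of other genes, so it is not the spread of the 3 replicates of that gene. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

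The samples and groups, the tests, the model without a replicate term, the same model with the replicate number as a block as its alternative, the rule for naming genes and most processing alternatives were chosen before the data were examined. The replicate numbers were then checked for pairing. Libraries with the same number deviated together from their group means, with correlations across genes of 0.69 to 0.95, and 9 of the 9 libraries correlated best with a library of their own number. The pairing thus comes from the data, since the labels do not say what a replicate number shares. Results with the number as a block are given beside those without it, and the alternatives combined with the block were added after the data were seen.

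The gene identifiers were matched to a RefSeq table of 59048 soybean genes (assembly Glycine_max v4.0), and 0 of 49777 matched. The table of scores does not pair its identifiers with names either. Gene lists fixed by words in gene names could therefore not be tested, and no gene function is given. Under the rule for this case at most 2 rising and 2 falling identifiers were named per comparison. They were the genes of largest fold change, with the block, among genes with an adjusted p under 0.05, a mean of at least 100 in the higher group, and no overlap between the 3 values of each group. The planned model without the block called 0 genes and would have named none, so the rule was applied to the block model. Genes of one family whose copies are nearly identical could not be separated from each other without sequences, so values of single identifiers are uncertain to that extent.

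Genes were assigned to classes of response from the 3 comparisons. Sustained genes were called in the same direction at both times against 0 h. Transient genes were called at 1 h and in the opposite direction between 1 h and 24 h, and late genes were called at 24 h against both earlier times and not at 1 h. Because both comparisons with 0 h use the same 0 h libraries, unchanged groups were simulated against those libraries 20 times. The models were tested on simulated data with known changes. With 200 changed genes in the comparison of 1 h with 0 h, the block model recovered 22% of 1.5-fold, 46.4% of 2-fold and 81.2% of 4-fold changes. The model without the block recovered 0%, 0% and 18.8%. Alternatives covered the pseudocount, the filter on low values, scaling, the libraries in the fit, the moderation, a 2-fold minimum, estimated depth, each library in turn and each replicate number in turn.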

Results

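Leaf RNA of soybean was sequenced before and during chilling at 4 °C to follow the early and the later transcript response. The leaves were the unifoliate pair of 2-week-old seedlings of the cultivar Williams 82, grown at 20 °C in 18 h of light and 6 h of darkness. Chilling began 4 h into the light period, and leaves were harvested after 0, 1 and 24 h, with 3 replicate libraries per time. The 0 h and 24 h leaves were harvested at the same hour of the light cycle. The 1 h leaves were harvested 1 h later in the light period, and no unchilled leaves of that hour were analysed here. The 24 h leaves were a day older than the 0 h leaves, and no unchilled leaves of that age were analysed either. The expression of 49777 genes was given as normalized read counts, and 41837 to 45808 genes were above 0 in a library. Library totals were 71.0 to 81.9 M normalized counts. The estimated depth of replicates 1, 2 and 3 was 29.6, 18.0 and 52.1 M reads at 0 h, 26.1, 26.4 and 58.3 M at 1 h, and 47.8, 67.7 and 49.5 M at 24 h.

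Transcript profiles differed far more between replicate numbers than between times in the cold. The replicate number accounted for 87.7% of the sum of squares of the log2 values and time for 5.1%. The first principal component, with 80.5% of the variance, separated the replicate 3 libraries from the other 6 at each time. Among the 28537 genes with a mean of at least 100, 42.3% differed by more than 2-fold between replicate 3 and the mean of replicates 1 and 2, whereas 4.3% did so between replicates 1 and 2. In replicate 3, 1649 of these genes were more than 8-fold higher and 540 more than 8-fold lower. A set of 52 genes had at least 100 normalized counts in all 3 libraries of replicate 3 and at most 3 in each of the other 6, and 4 genes showed the reverse. Across genes, which are not independent replicates, log2 values of libraries with the same number correlated at 0.967 to 0.989, and those of replicate 3 with replicates 1 or 2 at 0.753 to 0.817.

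**Figure D1:**
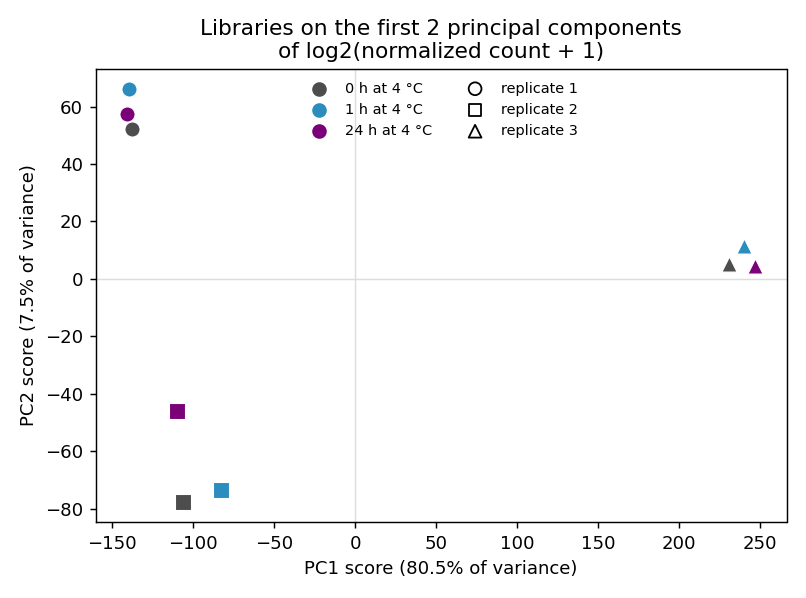
Scores of the 9 libraries on the first and second principal components of log2(normalized count + 1), with colours for hours at 4 °C and symbols for replicate numbers. The replicate 3 libraries lie apart along the first component (80.5% of the variance), and the second (7.5%) separates replicates 1 and 2.

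After 1 h at 4 °C, Glyma08g41640 and Glyma18g14490 showed the largest rises among 244 genes. These were called, had a mean of at least 100 normalized counts in the higher group and showed no overlap between the groups. Glyma08g41640 was at 5, 0 and 2 normalized counts in replicates 1, 2 and 3 at 0 h and at 514, 797 and 361 at 1 h. This was a log2 change of 7.66 ± 0.67 (moderated SE, n = 3 per group, limma adjusted p = 0.0047 with the replicate number as a block, as for the other named genes). Within replicates 1, 2 and 3 the log2 change was 6.42, 9.64 and 6.91. Its 0 h values were worth about 2 reads in replicate 1, 0 in replicate 2 and about 1 in replicate 3, and its log2 change was 8.12 with a pseudocount of 0.5 and 6.24 with a pseudocount of 5. Glyma18g14490 rose from 9.33 ± 2.31 to 1290 ± 400 normalized counts (mean ± SD, n = 3), a log2 change of 6.93 ± 0.48 (limma adjusted p = 0.0044). Its 0 h values were 8, 12 and 8 in replicates 1, 2 and 3, where 1 read was worth 2.52, 4.15 and 1.55. They thus rest on few reads. With pseudocounts of 0.5 and 5 its log2 change was 7 and 6.45. The largest falls, among 155 genes chosen in the same way, were in Glyma09g32120 and Glyma08g19390. Glyma09g32120 went from 107 ± 24.8 to 14.7 ± 11.5 normalized counts, a log2 change of -3 ± 0.46 (limma adjusted p = 0.0089), and Glyma08g19390 from 104 ± 46.2 to 17 ± 6.56, a log2 change of -2.49 ± 0.38 (limma adjusted p = 0.0089). With pseudocounts of 0.5 and 5 these changes were -3.06 and -2.64 for Glyma09g32120 and -2.53 and -2.25 for Glyma08g19390.

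With the replicate number as a block, 1742 of 38985 genes differed between 1 h and 0 h, 934 of them higher and 808 lower in the cold. Most of these changes were small, with a median of 1.39-fold. At least 2-fold changes were found in 87 of the genes that rose and 56 of those that fell, and at least 4-fold changes in 14 and 11. Abundant genes were called more often: 10.1% of the 11790 genes with a mean of at least 1000 were called, compared with 0.41% of the 10448 genes with a mean from 10 to under 100. The median SE of the log2 change was 0.08 in the abundant genes and 0.42 in the low ones. Without the block no gene passed (limma, 539 genes at an unadjusted p under 0.05, smallest adjusted p = 0.247), nor did any with the block when the trend and robust moderation was left out. The count fell to 7, 242 and 1288 genes without the libraries of replicate number 1, 2 and 3, and to 70 without the 1 h library of replicate 1, while equal library totals gave 1448 higher and 434 lower genes. The 4 named genes had adjusted p-values of 0.25 to 1 without the block and of 2.03e-06 to 0.19 over the alternatives with it.

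After 24 h at 4 °C, Glyma08g41640 was still high and Glyma14g37440 reached the highest level of the named genes. Glyma14g37440 was at 310 ± 136 normalized counts at 0 h, 3980 ± 1970 at 1 h and 11000 ± 6050 at 24 h (mean ± SD, n = 3), a log2 change of 5.02 ± 0.18 between 24 h and 0 h (SE, limma adjusted p = 0.00013). It had already risen by 3.64 ± 0.18 on the log2 scale at 1 h (limma adjusted p = 0.00099). Glyma08g41640 was at 176, 134 and 37 normalized counts in replicates 1, 2 and 3 at 24 h, a log2 change of 5.21 ± 0.67 from 0 h (limma adjusted p = 0.0088), which was 5.66 with a pseudocount of 0.5 and 3.85 with a pseudocount of 5. Glyma09g32120 and Glyma15g08270 fell most among the 194 called genes with a mean of at least 100 normalized counts at 0 h and no overlap between the groups. Glyma09g32120 was at 10.3 ± 10.2 normalized counts at 24 h, a log2 change of -3.62 ± 0.46 (limma adjusted p = 0.0039). Its 24 h values were 6, 3 and 22 in replicates 1, 2 and 3. With pseudocounts of 0.5 and 5 its log2 change was -3.72 and -3.05. Glyma15g08270 went from 100 ± 35.6 to 14.3 ± 8.62, a log2 change of -2.87 ± 0.43 (limma adjusted p = 0.0067). Its 24 h values were 5, 16 and 22 in replicates 1, 2 and 3. With pseudocounts of 0.5 and 5 its log2 change was -2.93 and -2.51.

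**Figure D2:**
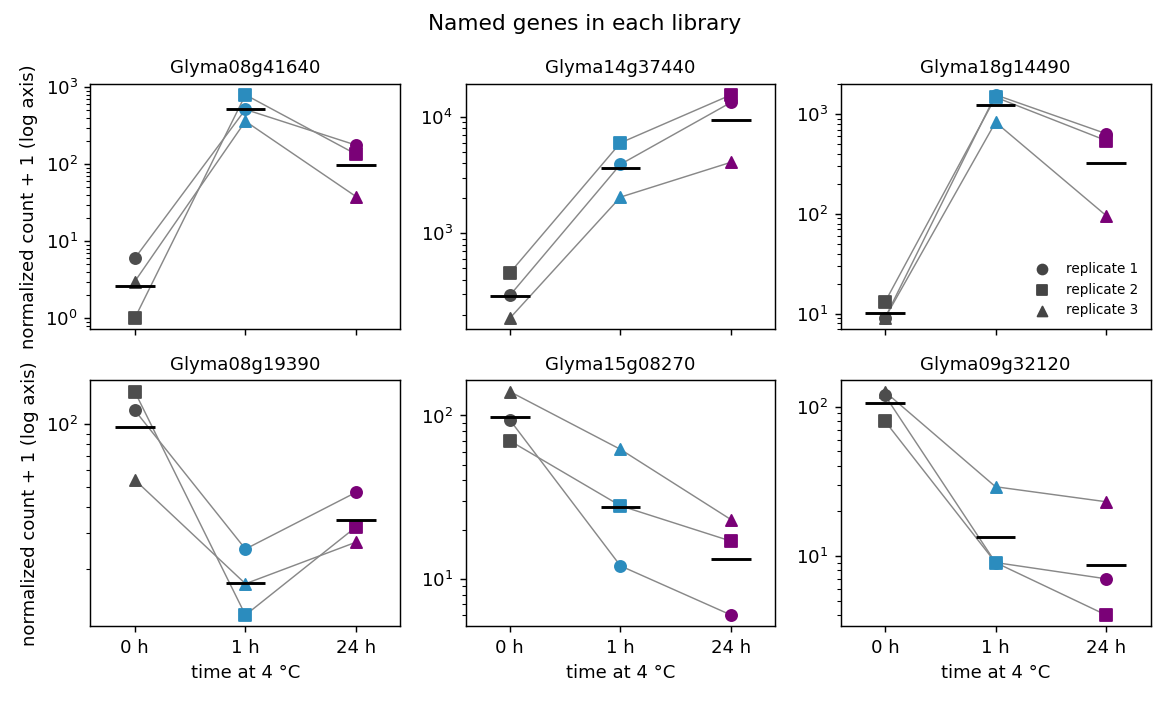
Normalized counts + 1 (log axis) of the 6 named genes in each library against hours at 4 °C, with symbols for replicate numbers, lines joining libraries of one number and bars at the mean of the log values. Glyma14g37440 was higher at 24 h than at 1 h in 3 of 3 replicate numbers, and Glyma08g41640 and Glyma18g14490 were lower.

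With the replicate number as a block, 1993 genes differed between 24 h and 0 h, harvested a day apart at the same hour of the light cycle. Of these genes 1173 were higher and 820 lower in the cold, with a median change of 1.38-fold. At least 2-fold changes were found in 76 of the genes that rose and 66 of those that fell, and at least 4-fold changes in 15 and 12. Called genes made up 11.7% of those with a mean of at least 1000 and 0.44% of those with a mean from 10 to under 100. Without the block no gene passed (limma, 549 genes at an unadjusted p under 0.05, smallest adjusted p = 1), and with the block 1 gene, Glyma14g37440, passed when the trend and robust moderation was left out. The count fell to 42 and 93 genes without the libraries of replicate number 1 and 2, was 1802 without those of number 3, and fell to 219 without the 24 h library of replicate 2, while equal library totals gave 921 higher and 1147 lower genes. The 4 named genes had an adjusted p of 1 without the block, and over the alternatives with it Glyma14g37440 had 9.72e-08 to 0.0284 and the others 0.00129 to 0.129.

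The genes called at 1 h and at 24 h overlapped. With the block 2596 genes were called at either time, and 1139 of them in the same direction at both, 700 higher and 439 lower. Independent lists of these sizes would share 45.1 genes, although lists compared with the same 0 h libraries are not independent. The 45.1 also takes every gene as equally likely to be called. Abundant genes were called more often at both times, which by itself raises the number shared. Without the block, or with it but without trend and robust moderation, no gene was sustained. With the block, 6, 66 and 727 were sustained without the libraries of replicate number 1, 2 and 3. No gene was called in opposite directions. With the block a further 603 genes were called at 1 h and not at 24 h, and 854 at 24 h and not at 1 h. Of these, 594 and 850 went in the same direction at the other time, which shares the 0 h libraries. Across the 28537 genes with a mean of at least 100, the mean log2 changes at the 2 times correlated at 0.793. Simulated noise of equal spread in all libraries, with no change, gave 0.5, a value that sharing the 0 h group fixes in advance. The covariance was 0.0704, compared with 0.0195 in the simulations, a difference of 0.0508. The simulations did not model noisier 0 h libraries, so they do not measure how much of the correlation comes from sharing them. The change at 1 h in one replicate number and the change at 24 h in another share no library, and these correlated at 0.28 on average, with a range of 0.20 to 0.34 over 6 pairs. The changes at 1 h in different numbers correlated at 0.29 and those at 24 h at 0.28.

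**Figure D3:**
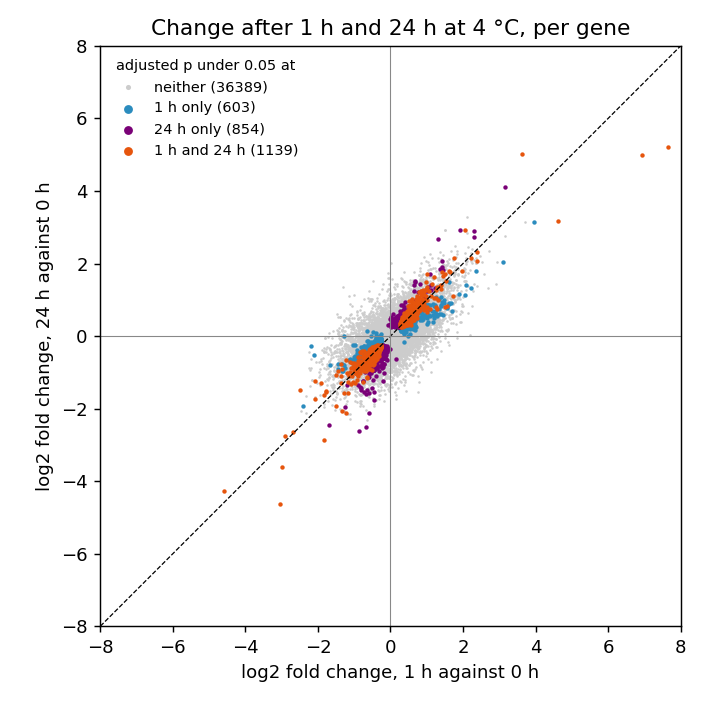
Log2 fold change of each of 38985 genes after 24 h (vertical axis) against that after 1 h (horizontal axis) at 4 °C, both relative to 0 h, coloured by the comparison in which the adjusted p with the replicate block was under 0.05. The dashed line marks equal changes, and the 1139 genes called at both times lie in the quadrants of a rise at both or a fall at both.

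Between 24 h and 1 h in the cold, no gene passed the test of the difference itself, so none was classed as transient or late. Glyma14g37440 was 1.38 ± 0.18 higher on the log2 scale at 24 h than at 1 h (SE, limma adjusted p = 0.56), in 3 of 3 replicate numbers. The difference of Glyma08g41640 was -2.45 ± 0.67 (limma adjusted p = 0.81) and that of Glyma18g14490 was -1.95 ± 0.48 (limma adjusted p = 0.8), both lower at 24 h in 3 of 3 replicate numbers. With the block 2211 genes, 5.7% of those tested, had an unadjusted p under 0.05 (limma, smallest adjusted p = 0.552), and without it 68 did. For genes with a mean of at least 100, the median 95% interval reached 0.94 on the log2 scale, or 1.92-fold, to each side without the block and 0.25, or 1.19-fold, with it. Across those genes the difference between 24 h and 1 h in different replicate numbers correlated at 0.00 on average, with a range of -0.07 to 0.11. Over the genes called at 1 h or 24 h against 0 h, which were chosen on the same libraries, it correlated at 0.48, with a range of 0.42 to 0.54. Without the libraries of replicate number 3, 3 genes passed with the block.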

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

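The alternatives combined with the replicate block, the thinning to one estimated depth and the removal of whole replicate numbers were chosen only after the results were seen. Without the block, 0 genes passed in each of the 3 comparisons under every alternative run, except without replicate number 3, where 39 genes passed at 1 h, 132 at 24 h and 29 were sustained. Adding the replicate block gave 1742, 1993 and 0 genes and 1139 sustained ones, and it changed no other class; the labels do not say what a number shares. With the block, both pseudocounts, both filters, the scalings and thinning gave 1315 to 1884 genes at 1 h and 1474 to 2119 at 24 h. Among the genes first called, 1 changed sign, at 24 h under quantile normalization. Thinning left 758 sustained genes. A 2-fold minimum left 143 and 142 genes by construction, and fits of only the 2 groups compared, with fewer samples, 734 and 1185. Without trend and robust moderation 0 and 1 genes passed and 0 were sustained. Without replicate number 1, 2 and 3, 7, 242 and 1288 genes passed at 1 h, 42, 93 and 1802 at 24 h, and 6, 66 and 727 were sustained; without number 3, 3 genes also told 24 h from 1 h and 2 were transient. Leaving out a single library left 70 to 1417 genes at 1 h, namely 257, 646 and 1417 without replicates 1, 2 and 3 of 0 h and 70, 1084 and 304 without those of 1 h. At 24 h it left 219 to 1705 genes, namely 421, 860 and 1705 without the 0 h replicates and 233, 219 and 1577 without those of 24 h. It left 68 to 976 sustained genes, 0 to 2 genes between 24 h and 1 h and 0 to 2 transient ones. Fewer samples enter these fits, but removals of the same size left very different counts. Sample number alone therefore does not account for the losses, and the cause was not tested further. Of the 8 gene results named, 8 lost their call without the block, 7 without trend and robust moderation, 7 without replicate number 1 and 4 without number 2. Leaving out replicate 1 of 0 h, of 1 h or of 24 h ended 2 of these calls each, and leaving out replicate 2 of 24 h ended 1. None reversed, and Glyma14g37440 kept its call at 24 h in 20 of 20 alternatives with the block (adjusted p 9.72e-08 to 0.0284). The count tests planned for recovered reads were not run because whole reads were not recovered, nor were the gene list tests because no identifier had a name. Depth limits genes with a mean under 100: their median SE at 1 h was 0.42, and counting of the estimated reads alone gave 0.404, compared with 0.08 and 0.044 for genes with a mean of at least 1000.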

Other observations

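The splits of the samples, the comparisons of replicate number 3 with the others, the correlations of the difference between 24 h and 1 h, the exchanged labels, the search for a labelled batch, the simulated recovery and the chromosome tests were chosen only after the results they bear on were seen.

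Genes called with the replicate block lay beside each other in the numbering of the identifiers more often than their expression level allows. At 1 h, 85 of 30787 neighbouring pairs had both members called in the same direction, compared with a mean of 34.4 and a highest value of 59 in 1000 shuffles within 10 classes of mean level (permutation p = 0.001, the smallest the shuffles can give). At 24 h, 89 pairs did so, compared with a mean of 45.9 and a highest value of 70 (permutation p = 0.001). Neighbouring copies that share reads and neighbouring genes that respond together are both candidate explanations, and neither was tested, because no gene sequences were used here. By the chromosome number in the identifier, 0 of 80 tests of the share of genes that rose or fell passed (Fisher's exact test, smallest adjusted p = 0.354).

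A few genes went from being listed at 0 to being listed above 0 or the reverse. From 0 h to 1 h, 50 genes were listed at 0 in all 3 libraries and then above 0 in all 3, and 34 showed the reverse. From 0 h to 24 h the numbers were 74 and 14. The 24 h libraries had an estimated 47.8 to 67.7 M reads and the 0 h libraries 18.0 to 52.1 M.

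Replicate number 3 stood apart from numbers 1 and 2 at each time. With every library thinned to one estimated depth, the SD of the log2 difference between number 3 and the mean of the others was 1.63 over 11790 genes with a mean of at least 1000, compared with 0.62 between numbers 1 and 2, which argues against depth. A few dominant genes would shift all others by about one constant, but over the 11690 of these genes outside the 100 most abundant the SD as deposited was 1.63, compared with 0.62 between numbers 1 and 2. A sequencing, library or growth batch and other plant material cannot be told apart, because the first component (80.5% of the variance) follows the number and the labels say nothing of what it shares. No biological explanation was tested, since the design names no group that follows the replicate number.

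No gene told 24 h from 1 h in the cold. In simulated data for this comparison with 200 genes changed, the block model called 93 genes and recovered 45.3% of 2-fold and 72.7% of 4-fold changes, and with 4000 changed it recovered 73.4% of 2-fold changes, and low power stays open for smaller or fewer changes. Against an exchange of the 1 h and 24 h libraries within one number, the difference between them correlated positively in every pair of numbers over 2969 genes chosen on the mean of both cold times (Pearson 0.31 to 0.40, Spearman 0.22 to 0.27), and the 1742 and 1993 genes called at 1 h and 24 h became 843 and 1587, 1534 and 964, or 1738 and 1653 when number 1, 2 or 3 was exchanged. The exchange was not excluded, since the lowest Pearson correlation was 0.19 without the 20 genes of largest difference, under the bound of 0.2 set for the test, and genes at least 2-fold apart the same way in the other numbers went that way in 4 of 5 cases in number 1, 6 of 9 in number 2 and 34 of 82 in number 3 (41.5%, exact 95% interval 30.7% to 52.9%). A response that changes little between 1 h and 24 h also stays open. The 2 groups were harvested at different hours of the light cycle, and any effect of the hour cannot be told apart from that of time in the cold.

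The 0 h libraries of replicates 1 and 2 were among the shallower ones, so depth was weighed as a source of the genes called against 0 h with the replicate block. After every library was thinned to the estimated depth of the shallowest, 1315 genes were called at 1 h and 1474 at 24 h, of which 1072 and 1265 were among the 1742 and 1993 called before. This argues against depth as the whole source. Thinning also made the library totals equal, and the genes that rose were then 1010 of 1315 at 1 h and 689 of 1474 at 24 h. A response to cold, to the hour of the day at 1 h and to a day of growth at 24 h stay open. Without unchilled leaves of the later times they cannot be told apart.

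Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. With the block, 1 of the 10 splits gave as many genes as the real one at 1 h, where the real value was 1742 and the highest of the others 0. At 24 h it was likewise 1 of 10, with 1993 genes and 0 in the highest of the others. At both times 3 of the others also put a library of each replicate number on both sides. In all of the others a real change with time enters the residual spread and lowers the count. Their 0 therefore does not tell whether the genes called in the real split are sound. Between 24 h and 1 h, 10 of 10 gave as many as the real 0, and the highest of the others, 24 genes, came from a split with both replicate 1 libraries on one side. Without the block all 10 splits of each comparison gave 0 genes, as did the real one.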
